A study of Mus musculus with 10 samples.

How the data were processed

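Hippocampal microglia sorted as CD45low CD11b+ cells from wild-type mice (4 libraries), 5xFAD mice on normal diet (3) and 5xFAD mice after depletion and repopulation (3) were profiled with Smart-Seq libraries, per the labels' protocols. The authors deposited a table of 19782 genes with 3 values per gene and library. Per the file headers and their values, the deposited estimated counts, also called expected counts, are reads assigned to genes and not normalised, and 20.1% of the nonzero values are not whole at a tolerance of 0.001. The deposited FPKM, per the file headers, are scaled for gene length and library size. The deposited TPM, per the file headers, are scaled likewise and sum to about the same total in every library. FPKM and TPM entered no test. The submitters' processing notes name HISAT, Bowtie2 and the genome build GRCm38.p6. The quantifier and the tool versions are not given in the sources used here. Genes carry Entrez identifiers, and 19725 matched RefSeq on GRCm38.p6, from which coordinates were taken. GC content and transcript length were those of the longest GENCODE transcript of each gene, found for 18974 genes. Estimated counts can split reads between near-identical genes, so values within multigene families (ribosomal proteins, Omt2a and Omt2b, the MHC) are uncertain.

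Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, statmod 1.5.0, DESeq2 1.42.0). After filterByExpr 12505 genes remained, tested with TMM normalisation, robust quasi-likelihood fits, 1 model of the 3 groups over all 10 libraries and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 27.3%. Fold changes used a prior count of 0.125, and standard errors are the absolute log2 fold change over the square root of F. A fold against a group with no count is a lower bound, set against 3 counts over that pooled group. Library totals ran from 18501136 to 23286814, and no pair of libraries of a group agreed within sampling noise. The first 2 principal components held 34.2% and 21.5% of the variance. On the second, wild-type 3 stood apart at -67, against 20.9 to 52.95 for the other wild-type libraries, and its mean correlation with its own group was 0.92, against 0.944 to 0.956.

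The tests and 27 gene lists, with markers of other cell types among them, were fixed before the data were examined. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over all lists, and again with an estimated correlation and with fry. A count adjusted over the list alone uses Benjamini-Hochberg adjustment within that list. The genes named follow a rule fixed with the lists. It takes the 10 largest changes in each direction among called genes whose groups do not overlap and whose level is above the lowest quartile, up to 4 members of each list by p, 12 genes of the study's subject, and the 10 largest among genes that reverse or persist. The text leaves some of them out, and some items are not reported here. Egg, Y-linked and neutrophil genes of the text other than Omt2b and Ngp, and Cldn5, Slc1a2, Mbp and Hba-a1, were named after values were seen. The correlation of fold changes between comparisons was set beside 50 simulations of unchanged groups, and overlaps beside those of independent lists. Unchanged groups give almost no calls, so they are no reference for an overlap.

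The gene test was tested on simulated data, with 200 of 12505 genes changed in each of 20 draws per comparison. For control against wild type 78% of 4-fold, 54.7% of 2-fold and 12.8% of 1.5-fold changes were recovered, with 5.6% false among the calls. For repopulated against control these were 78.1%, 48% and 9.7%, with 4.6% false. For repopulated against wild type they were 82.8%, 53.2% and 13.7%, with 5.8% false. The test was first run as a single draw, which for repopulated against control recovered 59.1% of 4-fold changes, under the 60% required beforehand. The 20 draws were taken after that, and the requirement was then applied to their mean. The first draw stayed the lowest for that comparison, and the highest was 89.4%. There 37.6% of 4-fold changes were recovered among the third of genes with the lowest expression, 97.3% in the middle and 99.5% among the highest. In each comparison camera called a simulated shifted list and 0 of 20 unshifted lists. The simulated genes were independent, so this does not test camera on correlated genes.

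Alternatives were DESeq2 factors and upper-quartile normalisation, DESeq2 and limma-voom as tests, no filter and a filter of 5 CPM in 3 libraries, a prior count of 0.5, each library left out, a replicate block, the compared groups alone, and other thresholds. Chosen after seeing the data were a term for Y-linked transcript status (4 genes, threshold 50 CPM of unscaled totals), leaving out the 3 libraries with near absent Y-linked transcripts (which left control 2 alone in the control group, assumed to vary like the other groups), a loess correction for GC content and transcript length (span 0.3, values for 97.8% of tested genes), leaving out wild-type 3 and control 2, and the split of the wild-type libraries.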

Results

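RNA was sequenced from microglia, the resident macrophages of the brain, sorted from the mouse hippocampus as CD45low CD11b+ cells. The 10 libraries fell into 3 groups. Wild-type mice on normal diet gave 4 libraries. Mice of the 5xFAD line, which carry human transgenes with familial Alzheimer disease mutations and form amyloid plaques, gave 3 libraries on normal diet (5xFAD control). Another 3 libraries came from 5xFAD mice whose microglia had been depleted and had returned (5xFAD repopulated). Depletion used chow with 290 mg/kg of PLX3397, an inhibitor of the CSF1 receptor on which microglia depend for survival, fed for 1 month from 4 months of age. Normal diet followed for 1 month. A repopulated wild-type group was not analysed here. The libraries held 18501136 to 23286814 estimated counts, and 12505 genes were tested. The labels do not state that the libraries of a group come from separate animals, so p-values measure the spread between these samples, which may be technical. Transcripts of 4 Y-linked genes were near absent in wild-type 2, control 1 and control 3 (5.12 to 16.01 CPM of unscaled totals) and present in the other libraries (341.87 to 483.77). Leaving these 3 libraries out, chosen after seeing the data, left 3 wild-type, 3 repopulated and 1 control library, control 2, which was then assumed to vary like the other groups. Values given below with control 2 as the only control library are from that fit and rest on control 2 alone for the control group. Levels are library-scaled counts (CPM) as mean ± SD over the 4 wild-type, 3 control or 3 repopulated libraries. Folds and edgeR adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

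The first comparison asked how microglia of 5xFAD mice on normal diet differed from wild-type microglia. Control 5xFAD microglia had far more transcripts of the disease-associated programme, which microglia near plaques express, and fewer transcripts of 15 of 29 homeostatic genes. With an estimated correlation neither list held its call, at adjusted p = 0.0581 and 0.229. Apoe, which encodes the lipid carrier apolipoprotein E (Entrez 11816, chromosome 7, 19696244 to 19701310 in GRCm38.p6), rose 13.9-fold, from 1026 ± 363 to 14310 ± 5584 CPM. Cst7, which encodes the cathepsin inhibitor cystatin F (Entrez 13011, chromosome 2, 150570415 to 150578944), rose 127-fold, from 9.94 ± 4.53 to 1263 ± 199 CPM (log2 fold change 6.99, SE 0.33, edgeR adjusted p = 7.54e-09). Tmem119, a surface protein of resident microglia (Entrez 231633, chromosome 5, 113793729 to 113800396), fell 2.45-fold, from 1569.7 ± 291 to 640.1 ± 121 CPM (edgeR adjusted p = 0.000137).

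Of the 44 disease-associated genes, 41 rose and 3 did not pass, and 42 rose adjusted over the list alone (camera adjusted p = 5.01e-41, and adjusted p = 0.0581 with an estimated correlation). Igf1, the insulin-like growth factor (Entrez 16000, chromosome 10, 87858265 to 87937047), rose 70.3-fold to 374 ± 7.56 CPM. Lpl, the lipoprotein lipase, rose 26.3-fold to 526 ± 38.8 CPM, and Clec7a, the beta-glucan receptor dectin-1, 19.2-fold to 765 ± 24.9 CPM. Trem2, a lipid-sensing receptor, rose 1.82-fold, from 1508 ± 89.4 to 2739 ± 623 CPM (edgeR adjusted p = 0.00153, and 0.172 with control 2 as the only control library, 6.6e-08 to 0.172 over all alternatives). Baiap2l2 and Dkk2 of the same list had no count in any wild-type library. They were at least 574-fold and at least 514-fold higher in control microglia, against a floor of 3 counts over the pooled wild-type group. Such floors cover counting error only. Hpse, which encodes heparanase and is on no list, rose 249-fold to 30.9 ± 9.61 CPM.

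Of 29 homeostatic genes 15 fell and 14 did not pass, and 1 rose and 15 fell adjusted over the list alone (camera adjusted p = 0.000253, and adjusted p = 0.229 with an estimated correlation). Crybb1, a crystallin gene, fell 2.73-fold, Slc2a5, a fructose transporter gene, 2.02-fold, and Cx3cr1, the fractalkine receptor gene, 1.78-fold. P2ry12, the ADP receptor gene, went from 7993 ± 1006 to 5195 ± 176 CPM (edgeR adjusted p = 0.0246). Without wild-type 2, control 1 or control 3 its edgeR adjusted p was 0.0605 to 0.0915, and without all 3, with control 2 as the only control library, 0.313 (0.000505 to 0.313 over all alternatives). Csf1r, which encodes the target of PLX3397, went from 3984 ± 715 to 2608 ± 463 CPM (edgeR adjusted p = 0.0239). Without wild-type 1 or 4 or control 1 or 2 its edgeR adjusted p was 0.0633 to 0.0856, and with the GC and length correction 0.0564 (0.0019 to 0.0856 over all alternatives).

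Many translation and metabolic genes rose. Of 77 cytosolic ribosomal protein genes 70 rose, and 76 rose adjusted over the list alone, with Rpl5 2.25-fold higher (camera adjusted p = 9.71e-33, and adjusted p = 0.252 with an estimated correlation). Of 68 oxidative phosphorylation genes 34 rose, and 42 rose adjusted over the list alone, with Ndufa1, a complex I subunit gene, 4.16-fold higher (camera adjusted p = 1.67e-11, and adjusted p = 0.411 with an estimated correlation). Changes in this comparison followed GC content across tested genes (rho -0.263). The median log2 fold change of the oxidative phosphorylation list was 0.54, and 0.28 with the GC and length correction (camera adjusted p = 1.5e-06). Of 28 glycolysis and hypoxia genes 15 rose, and 17 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.23e-07, and adjusted p = 0.229 with an estimated correlation). Among them were Hif1a, the oxygen-regulated transcription factor gene, at 4.49-fold and Pgk1, a glycolytic enzyme gene, at 3.55-fold. Of 24 cholesterol synthesis genes 12 rose, and 14 rose adjusted over the list alone, with Insig1, which encodes a sterol-sensing restraint on synthesis, at 5.22-fold and Sqle, the squalene epoxidase gene, at 6.09-fold. Of the 13 lists called in this comparison it was the 1 whose call held with an estimated correlation (camera adjusted p = 2.77e-06, and adjusted p = 0.0253 with an estimated correlation).

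Many lysosomal and lipid genes rose as well. Of 46 lysosome genes 23 rose and 1 fell, and 27 rose and 2 fell adjusted over the list alone, with Ctsl, the cathepsin L gene, at 3-fold and Npc2, a cholesterol transfer protein gene, at 2.61-fold (camera adjusted p = 4.96e-09, and adjusted p = 0.333 with an estimated correlation). Of 36 lipid handling genes 17 rose and 3 fell, and 21 rose and 5 fell adjusted over the list alone, with Fabp5, a fatty acid binding protein gene, at 48.5-fold (camera adjusted p = 2.77e-06, and adjusted p = 0.229 with an estimated correlation). Of 35 phagocytic receptor and complement genes 9 rose and 2 fell, and 10 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0446, and adjusted p = 0.459 with an estimated correlation). Its camera adjusted p was 0.0706 without wild-type 1, 0.122 without wild-type 2, 0.0766 without control 1 and 0.0971 without control 3. It was 0.559 with control 2 as the only control library (0.00463 to 0.559 over all alternatives), and the median log2 fold change was -0.09, against 0.22 with all libraries. This median was 0.03, 0.04 and 0.09 without control 1, 2 and 3 and 0.12 without repopulated 2 or 3.

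Of 38 interferon response genes 18 rose, and 22 rose adjusted over the list alone, among them Ifi204 at 4.64-fold and Slfn5 at 3.01-fold (camera adjusted p = 6.28e-10, and adjusted p = 0.411 with an estimated correlation). Of 24 antigen presentation genes 8 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone, with B2m, the light chain gene of MHC class I, at 2.41-fold (camera adjusted p = 0.000711, and adjusted p = 0.47 with an estimated correlation). The median log2 fold change of that list was 0.67, and 0.21 with control 2 as the only control library, with a camera adjusted p of 0.27 (3.97e-06 to 0.47 over all alternatives). Directional fry gave the list an adjusted p of 0.0512 with all libraries. Of 38 cell cycle genes 9 rose, and 9 rose adjusted over the list alone, including Mki67 at 2.77-fold and Cdk1 at 4.16-fold (camera adjusted p = 5.15e-05, and adjusted p = 0.333 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 rose 16.2-fold and 6.91-fold. Their list of 32 inflammatory genes, with 10 up and 2 down, and 13 rose and 5 fell adjusted over the list alone, did not pass (camera adjusted p = 0.0834), and had 0.0326 without the expression filter and 0.00154 by directional fry (0.00154 to 0.358 over all alternatives).

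The series title names BDNF signalling. Bdnf, the gene of brain-derived neurotrophic factor (Entrez 12064, chromosome 2, 109674700 to 109727043), had 37 counts over the 4 wild-type, 6 over the 3 control and 13 over the 3 repopulated libraries. Wild-type 1, 2, 3 and 4 held 8, 0, 23 and 6 of the 37. These counts lie under the expression filter. Without the filter Bdnf had an edgeR adjusted p of 0.489 for control against wild type, 0.894 for repopulated against control and 0.817 for repopulated against wild type. A difference in Bdnf was not detectable with counts this low and this uneven between libraries. Ntrk2, which encodes its receptor TrkB, was at 3.42 ± 3.19, 1.23 ± 0.384 and 1.88 ± 0.601 CPM in wild-type, control and repopulated libraries, with an edgeR adjusted p of 0.113, 0.649 and 0.573 in the same order of comparisons. It was at 8.21 CPM in wild-type 3 and 1.78 to 1.89 CPM in the other wild-type libraries. Wild-type 3 also held the most Snap25 (28.19 CPM) and Slc1a2 (42.18 CPM), genes of neurons and astrocytes. Whether its Ntrk2 came from such cells was not tested. Its log2 fold changes of control and repopulated against wild-type microglia were -1.47 and -0.86, and -0.57 and 0.05 without wild-type 3, where the edgeR adjusted p was 0.405 and 0.983 (0.0712 to 0.478 over all alternatives and 0.446 to 0.983 over all alternatives). Of 37 BDNF-TrkB pathway genes 1 rose and 5 fell in control microglia, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0571). Apart from Bdnf and Ntrk2 the list is mainly of general signalling genes, so it does not measure BDNF signalling alone. The kinase genes Prkca and Rps6ka1 fell 2.25-fold and 2.1-fold, with an edgeR adjusted p of 0.059 for Prkca with control 2 as the only control library (1.38e-08 to 0.059 over all alternatives). Without wild-type 3 this list had a camera adjusted p of 0.0126 for control against wild type, and with upper-quartile scaling 0.0497 (0.012 to 0.477 over all alternatives). Of 23 neurotrophic factor genes 5 rose, and 5 rose adjusted over the list alone, among them the growth factor genes Fgf2 at 2.95-fold, Pdgfa at 1.98-fold and Grn at 1.71-fold. With control 2 as the only control library Grn had an edgeR adjusted p of 0.182, against 0.00364 with all (2.19e-06 to 0.182 over all alternatives). The list had a median log2 fold change of -0.07 and a mean of 0.40 (camera adjusted p = 0.0894). With Y-linked transcript status as a term it had a median of 0.02 and a camera adjusted p of 0.0347, and with the GC and length correction 0.17 and 0.022 (0.000727 to 0.27 over all alternatives).

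In all, 2264 genes changed between control and wild-type microglia, 1259 up and 1005 down. The count was 1315 without control 1 (834 up and 481 down) and 1465 without control 2 (905 up and 560 down). With control 2 as the only control library, against 3 wild-type libraries, 1201 genes changed, 692 up and 509 down. Markers of neurons fell as a list of 9 tested genes, 1 of them called, and 3 fell adjusted over the list alone (camera adjusted p = 0.00878, and adjusted p = 0.411 with an estimated correlation). Its camera adjusted p was 0.149 with control 2 as the only control library (0.00289 to 0.411 over all alternatives), and directional fry gave 0.0521 with all libraries. Its median log2 fold change was -1.83, and -0.68 without wild-type 3. The called gene was Snap25, a synaptic gene, at 28.19 CPM in wild-type 3 and 5.03 to 6.65 CPM in the other wild-type libraries (edgeR adjusted p = 0.018, and 0.0735 to 0.0799 without control 3 or 1, 0.000856 to 0.27 over all alternatives). Its log2 fold change was -2.04, and -1.10 without wild-type 3. Wild-type 3 also held more transcripts of other cell types than the other wild-type libraries: the astrocyte gene Slc1a2 was at 42.18 CPM (3.06 to 5.84 in the others), the oligodendrocyte gene Mbp at 48.11 CPM (8.98 to 13.99 in the others) and the erythrocyte gene Hba-a1 at 128.58 CPM (0 to 8.78 in the others). With all libraries none of the 3 was called. Without wild-type 3 Mbp was higher in control and repopulated than in wild-type microglia, with log2 fold changes of 0.90 and 0.80 against 0.08 and -0.02 and an edgeR adjusted p of 0.00474 and 0.0252 (0.00474 to 0.963 over all alternatives and 0.0215 to 1 over all alternatives). With a replicate block Hba-a1 was lower in both (3.9e-06 to 0.736 over all alternatives and 4.22e-06 to 0.85 over all alternatives). App, which encodes the amyloid precursor protein, was at 117 ± 12.2 and 162 ± 7.61 CPM (edgeR adjusted p = 0.0139, 0.0622 without control 1 and 0.0503 with a replicate block). Its log2 fold change was 0.34 with control 2 as the only control library, and 0.46 with a replicate block. The 5xFAD transgenes include a human form of App, and reads from it were not told apart from those of the mouse gene.

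**Figure D1:**
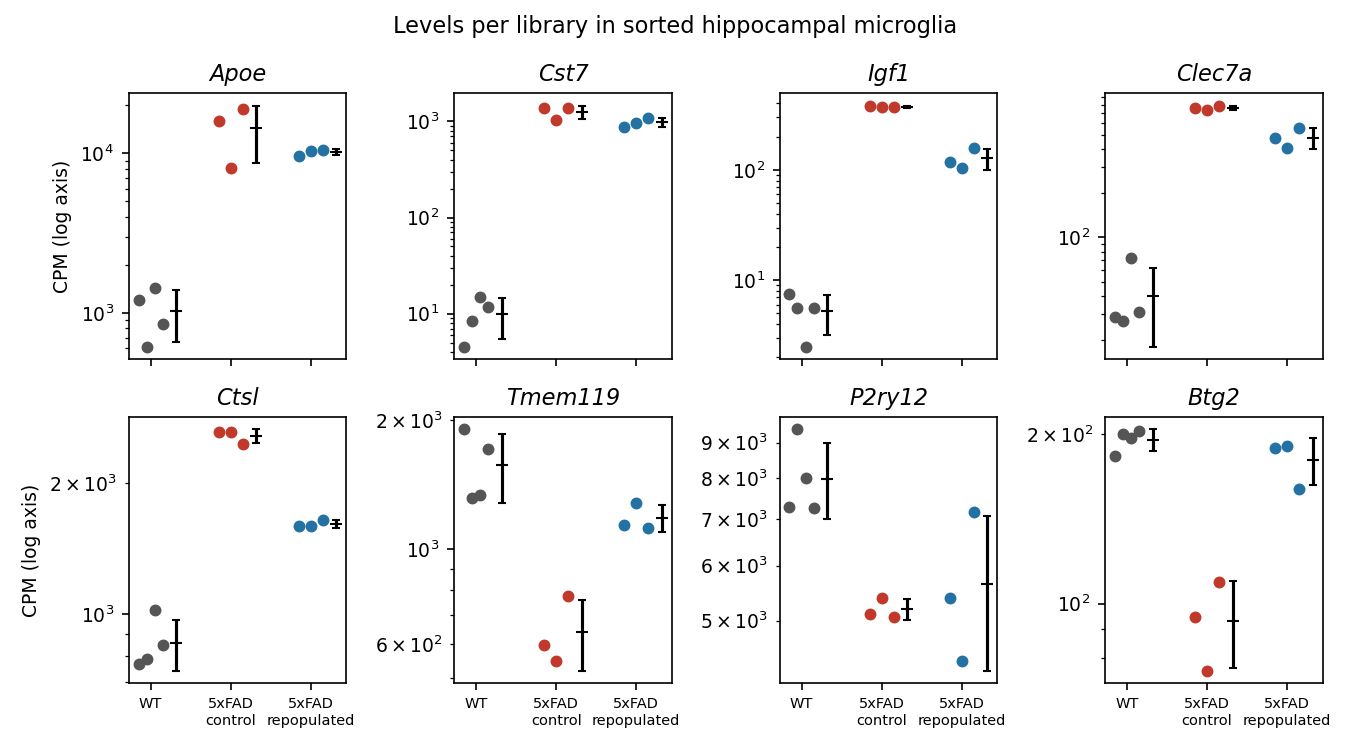
Levels of 8 genes per library in CPM on a log axis, by group, with the mean and SD beside the points of 4 wild-type, 3 control and 3 repopulated libraries. Igf1 went from 5.31 CPM in wild-type to 374 CPM in control and 127 CPM in repopulated microglia, and Tmem119 from 1569.7 to 640.1 and 1181 CPM.

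The second comparison asked what differed between repopulated and control microglia within 5xFAD mice. Repopulated microglia had lower levels of some genes raised in control microglia and higher levels of some that were reduced there. Iqgap1, which encodes a cytoskeletal scaffold (Entrez 29875, chromosome 7, 80711583 to 80815549), fell 2.65-fold, from 163 ± 26.4 to 61.3 ± 8.22 CPM (log2 fold change -1.41, SE 0.17, edgeR adjusted p = 0.00618). Igf1 fell 2.94-fold, from 374 ± 7.56 to 127 ± 27.8 CPM (edgeR adjusted p = 0.0158). Ncs1, which encodes a calcium sensor, rose 3.69-fold, from 8.56 ± 4.36 to 31.6 ± 2.53 CPM (edgeR adjusted p = 0.0119).

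In total 71 genes changed, 44 up and 27 down. Bcl9l rose 4.11-fold, Tsc22d3, a glucocorticoid-induced gene, 3.2-fold, Rab3il1 2.54-fold and Btg2, an antiproliferative early response gene, 1.93-fold. Mamdc2 fell 2.13-fold, Gas2l3 2.49-fold, Insig1 2.19-fold and Cybb, a subunit gene of the phagocyte NADPH oxidase, 2.17-fold. Cd209a, a C-type lectin gene of dendritic cells and some macrophages, fell 8.86-fold, from 37.1 ± 21.2 to 4.18 ± 0.405 CPM (edgeR adjusted p = 0.0351). Omt2b, an oocyte transcript (Entrez 382088, chromosome 9, 78328030 to 78329620), had no count in the control libraries and 7.56 ± 2.85 CPM in the repopulated libraries, at least 155-fold higher. With Omt2a, Tcl1 and Btg4, named after their values were seen, it made 4 egg transcripts among the 44 genes that rose. Expression of these 4 by repopulated microglia cannot be told apart from carry-over of egg material. Omt2a (edgeR adjusted p 0.0708 to 0.115) and Btg4 (0.0713 to 0.134) lost their calls without control 1 or 2 or any 1 of the repopulated libraries. Tcl1 lost its call without control 1 or repopulated 2 (0.0529 to 0.0792). The edgeR adjusted p of Igf1 was 0.0708 to 0.146 without control 1 or 2 or repopulated 1 or 2. The same 4 libraries ended the calls of Ncs1 (0.0708 to 0.0918), Bcl9l (0.0708 to 0.115), Tsc22d3 (0.0708 to 0.134), Rab3il1 (0.0836 to 0.134), Btg2 (0.0708 to 0.134), Gas2l3 (0.0529 to 0.127) and Insig1 (0.0766 to 0.185). Cybb lost its call also without repopulated 3 (0.0722 to 0.174), and Cd209a without repopulated 3 or wild-type 4 (0.0518 to 0.267). Of single libraries, only repopulated 2 ended the calls of Iqgap1 and Omt2b when left out (0.0622 for both, 2.09e-11 to 0.0622 over all alternatives for Iqgap1 and 4.4e-05 to 0.109 over all alternatives for Omt2b), and Mamdc2 lost its call without control 1 or repopulated 2 (0.0608 to 0.0792). With control 2 as the only control library the calls of Igf1 (0.0655, 1.74e-07 to 0.146 over all alternatives), Tsc22d3 (0.0958, 1.22e-06 to 0.134 over all alternatives), Cybb (0.0605, 1.8e-05 to 0.174 over all alternatives) and Btg4 (0.0642, 0.00213 to 0.134 over all alternatives) ended. Cd209a had 0.0775 by limma-voom and 0.0767 without the expression filter (4.07e-05 to 0.267 over all alternatives).

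Most disease-associated genes did not pass the test between the 5xFAD groups. Of the 44, 4 fell and 40 did not pass, and 11 fell adjusted over the list alone. As a list they fell, with a median log2 fold change of -0.37 (camera adjusted p = 4.31e-07, and adjusted p = 0.753 with an estimated correlation). The median was -0.06 with control 2 as the only control library, with a camera adjusted p of 0.751 (1.84e-15 to 0.753 over all alternatives). The mean log2 level of the list, relative to all libraries, was 1.04 in control 2 and 1.52 and 1.63 in control 1 and 3. Directional fry gave the list 0.229 with all libraries. Apoe was at 14310 ± 5584 and 10155 ± 466 CPM (edgeR adjusted p = 0.403), and Cst7 at 1263 ± 199 and 975 ± 104 CPM (edgeR adjusted p = 0.514). Clec7a was at 765 ± 24.9 and 479 ± 77.8 CPM (edgeR adjusted p = 0.249, 0.0292 without wild-type 3, 0.0257 to 0.602 over all alternatives). The interferon list fell with 1 of 38 genes called, Slfn5 at 2.29-fold, and 2 fell adjusted over the list alone (camera adjusted p = 9.89e-06, and adjusted p = 0.753 with an estimated correlation, and 0.505 by directional fry). Slfn5 had an edgeR adjusted p of 0.0215, and of 0.0713 to 0.174 without control 1 or 2 or any 1 of the repopulated libraries.

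The 77 ribosomal protein genes fell as a list, with a median log2 fold change of -0.38 (camera adjusted p = 4.68e-15, and adjusted p = 0.753 with an estimated correlation). The 68 oxidative phosphorylation genes did too, with a median of -0.25 (camera adjusted p = 3.72e-05, and adjusted p = 0.753 with an estimated correlation). Directional fry gave adjusted p-values of 0.229 and 0.505, and the GC and length correction gave medians of -0.24 and -0.11. In each of these lists edgeR called 0 genes, with 0 adjusted over the list alone. At an unadjusted p under 0.05, 41 ribosomal genes were lower, and 16 oxidative phosphorylation genes were lower and 2 higher. DESeq2 called 12 and 3 lower, and limma-voom 0 and 0.

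Of 29 homeostatic genes 1 rose, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0689). It was Tmem119, at 1.85-fold, from 640.1 ± 121 to 1181 ± 85.8 CPM (edgeR adjusted p = 0.0468). Of 37 BDNF-TrkB pathway genes 1 rose, Rps6ka1 at 1.75-fold (edgeR adjusted p = 0.0496), and 2 rose adjusted over the list alone (camera adjusted p = 0.0689). The edgeR adjusted p was 0.0531 to 0.267 for Tmem119 and 0.0531 to 0.267 for Rps6ka1 without wild-type 2 or 4, control 1 or 2, or any 1 of the repopulated libraries. Tmem119 had 0.0564 with the GC and length correction (0.000111 to 0.267 over all alternatives), and Rps6ka1 0.0505 with upper-quartile scaling and 0.0507 with DESeq2 factors (0.000797 to 0.267 over all alternatives). The homeostatic list had a camera adjusted p of 0.0286 without control 2 and 0.00868 without repopulated 2 (0.00868 to 0.753 over all alternatives). The BDNF-TrkB list had 0.0328 without wild-type 3, 0.0245 without control 2 and 0.0216 without repopulated 3 (0.00827 to 0.753 over all alternatives).

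Igf1 was the called gene of 23 neurotrophic factor genes (2 fell adjusted over the list alone, camera adjusted p = 0.28) and Fabp5 that of 36 lipid handling genes (1 rose and 2 fell adjusted over the list alone, camera adjusted p = 0.412). Insig1 was the called gene of 24 cholesterol synthesis genes (2 fell adjusted over the list alone, camera adjusted p = 0.405) and Btg2 that of 36 stress and immediate early genes (3 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.164, and 0.022 without repopulated 3, 0.022 to 0.753 over all alternatives). Lysosome genes (camera adjusted p = 0.249) had 1.83e-05, median -0.20, without control 2, but 0.0284, median 0.33, with control 2 as the only control library (1.83e-05 to 0.94 over all alternatives). Neutrophil markers (camera adjusted p = 0.336) had 3.85e-05, median 2.56, without control 2, but 0.0327, median -1.08, with control 2 as the only control library and 0.0415, median -1.14, with Y-linked transcript status as a term (3.85e-05 to 0.76 over all alternatives). Control 2 held 149.05 CPM of the neutrophil transcript S100a8, and control 1 and 3 8.97 and 8.25. Glycolysis and hypoxia genes (camera adjusted p = 0.265) had 0.00286, median -0.20, without control 2 (0.00286 to 0.753 over all alternatives).

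Markers of border-associated macrophages (camera adjusted p = 0.0928) had 0.0171 without control 3 and 0.0216 without repopulated 3. They had 0.00689, median -0.59, with Y-linked transcript status as a term and 0.00715, median -0.89, with control 2 as the only control library (0.00689 to 0.753 over all alternatives). Markers of monocytes and recruited macrophages (camera adjusted p = 0.249) had 0.00103, median -0.90, and 0.036, median -0.65, in the same order (0.00103 to 0.753 over all alternatives). Oligodendrocyte markers (camera adjusted p = 0.219) had 0.0286, median 2.13, with control 2 as the only control library (0.0286 to 0.753 over all alternatives). Without wild-type 3 and control 2 cell cycle genes (camera adjusted p = 0.297) had 0.0398, median -0.37, phagocytic genes (camera adjusted p = 0.336) 0.044, median -0.19, and neuron markers (camera adjusted p = 0.265) 0.044, median 0.66 (0.0398 to 0.789 over all alternatives, 0.044 to 0.772 over all alternatives and 0.044 to 0.912 over all alternatives).

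The count of 71 genes was 124, 46, 328 or 47 without wild-type 1, 2, 3 or 4, and 2, 4 or 178 without control 1, 2 or 3. It was 4, 0 or 42 without repopulated 1, 2 or 3. For the 0 by edgeR, 1321 genes had an unadjusted p under 0.05, and other tools were not run without that library. With all libraries DESeq2 called 698, 329 up and 369 down, so that more fell than rose, and limma-voom 125, 67 up and 58 down. Y-linked transcripts were near absent in control 1 and 3 and present in control 2 and the repopulated libraries. This status, and any difference in sex that it marks, was thus partly confounded with repopulated against control. With this status as a term, chosen after seeing the data, 1 gene was called, Iqgap1, and with control 2 as the only control library 388, 234 up and 154 down.

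**Figure D2:**
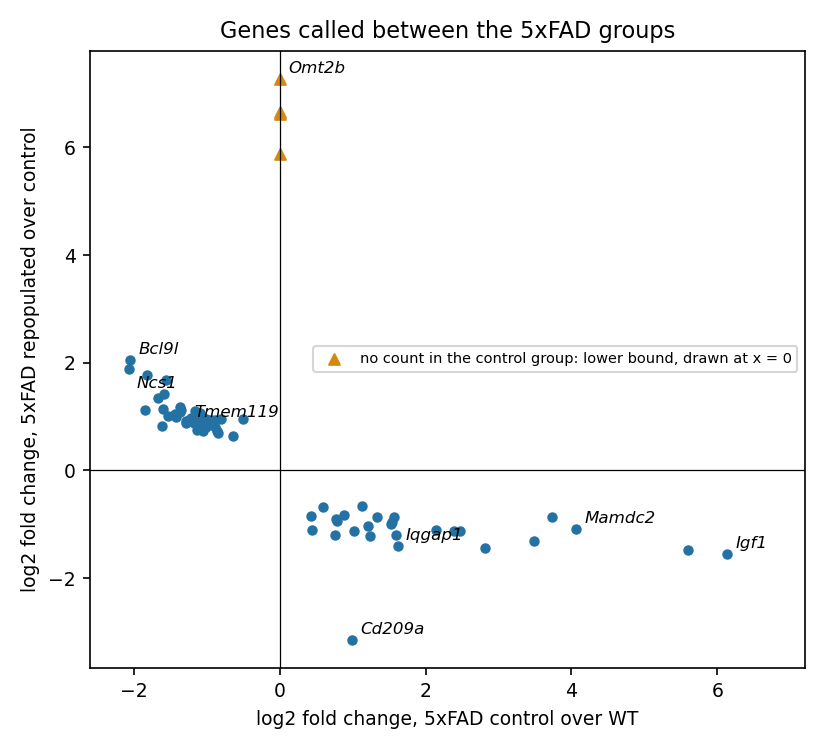
Each point is 1 of the 71 genes called between repopulated and control 5xFAD microglia, with its log2 fold change of control over wild type on the x axis and of repopulated over control on the y axis, and triangles, drawn at x = 0, are genes with no count in the control group at their lower bound. Igf1 lies at 6.14 and -1.55, and Ncs1 at -2.08 and 1.88.

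Most genes called in the second comparison were called with the opposite sign in the first. Of the 71 genes, 64 were. Of these, 24 had risen in control microglia, among them Igf1, Fabp5, Mamdc2, Lilrb4a, Gas2l3, Cybb and Insig1, and 40 had fallen, among them Ncs1, Bcl9l, Rab3il1 and Btg2. Fabp5 had an edgeR adjusted p of 0.0496 between the 5xFAD groups, and of 0.0536 to 0.276 without wild-type 2 or 4 or any 1 of the 5xFAD libraries. Lilrb4a, an inhibitory receptor gene, had 0.0496, and 0.0622 to 0.233 without wild-type 4 or any 1 of the 5xFAD libraries. These were 0.142 and 0.149 with control 2 as the only control library, and with upper-quartile scaling 0.0512 and 0.0505 (0.000281 to 0.276 over all alternatives and 0.00039 to 0.233 over all alternatives). Mamdc2 was at 5.12 ± 0.417, 86 ± 7.04 and 40.4 ± 2.07 CPM in wild-type, control and repopulated libraries, and Ncs1 at 36.2 ± 5.37, 8.56 ± 4.36 and 31.6 ± 2.53 CPM. Of the 64 genes, 12 still differed between repopulated and wild-type microglia. Independent lists would share 2.7 and 3.5 per direction, but the control libraries enter both comparisons with opposite signs. They are too few to split, so the number of opposite genes has no reference free of them. Over the 12505 tested genes the log2 fold changes of these comparisons had r = -0.514, against -0.545 for simulated unchanged groups (range -0.600 to -0.508). Their covariance was -0.296, against -0.122 simulated. These are relations across genes, which are not independent replicates. The count of opposite genes was 109, 42, 300 or 41 without wild-type 1, 2, 3 or 4, 1, 2 or 165 without control 1, 2 or 3, and 2, 0 or 40 without repopulated 1, 2 or 3.

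The third comparison set repopulated 5xFAD against wild-type microglia. Genotype and depletion with repopulation differ together in it, and without a repopulated wild-type group they cannot be separated. Repopulated microglia still held far more disease-associated transcripts than wild-type microglia. Apoe was 9.9-fold higher (10155 ± 466 against 1026 ± 363 CPM). Cst7 was 98-fold higher (975 ± 104 against 9.94 ± 4.53 CPM, log2 fold change 6.61, SE 0.32, edgeR adjusted p = 2.61e-08), and Itgax, the gene of integrin CD11c, 14.5-fold. Tmem119 was at 1181 ± 85.8 against 1569.7 ± 291 CPM (edgeR adjusted p = 0.247).

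Of the 44 disease-associated genes 41 rose, and 42 rose adjusted over the list alone (camera adjusted p = 6.58e-60, and adjusted p = 0.0205 with an estimated correlation). Igf1 was 23.9-fold, Lpl 15-fold, Clec7a 12-fold and Trem2 1.77-fold higher than in wild-type microglia, and Baiap2l2 and Dkk2 at least 460.4-fold and at least 283-fold. Of 24 cholesterol synthesis genes 9 rose, and 14 rose adjusted over the list alone, with Insig1 at 2.38-fold and Sqle at 5.73-fold (camera adjusted p = 1.85e-09, and adjusted p = 0.00605 with an estimated correlation). Of 14 lists called, these 2 held with an estimated correlation. Of 46 lysosome genes 15 rose, and 22 rose adjusted over the list alone, with Ctsl at 1.88-fold (camera adjusted p = 5.37e-13, and adjusted p = 0.228 with an estimated correlation). Of 36 lipid handling genes 11 rose, and 15 rose and 1 fell adjusted over the list alone, with Fabp5 at 17.5-fold (camera adjusted p = 5.62e-11, and adjusted p = 0.0912 with an estimated correlation). Of 28 glycolysis and hypoxia genes 12 rose, and 16 rose adjusted over the list alone, with Egln3, an oxygen-sensing hydroxylase gene, at 39.1-fold, and 60.7-fold without wild-type 4 (camera adjusted p = 1.61e-10, and adjusted p = 0.0912 with an estimated correlation).

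Of 77 ribosomal protein genes 25 rose, and 55 rose adjusted over the list alone (camera adjusted p = 3.33e-27, and adjusted p = 0.228 with an estimated correlation). Of 68 oxidative phosphorylation genes 3 rose, and 3 rose adjusted over the list alone (camera adjusted p = 3.25e-08, and adjusted p = 0.528 with an estimated correlation). Of 24 antigen presentation genes 5 rose, and 13 rose adjusted over the list alone, with B2m at 1.88-fold (camera adjusted p = 2.23e-06, and adjusted p = 0.337 with an estimated correlation). Without repopulated 3 B2m had an edgeR adjusted p of 0.0585, and without the 3 libraries with near absent Y-linked transcripts 0.056 (2.01e-05 to 0.0585 over all alternatives). Of 38 interferon genes 3 rose, and 5 rose adjusted over the list alone, with Ifi204 at 2.31-fold (camera adjusted p = 5.68e-06, and adjusted p = 0.528 with an estimated correlation). Without the same 3 libraries Ifi204 had an edgeR adjusted p of 0.0801 (8.43e-05 to 0.0801 over all alternatives). The mean log2 level of the interferon list, relative to all libraries, was 0.26 in wild-type 4, above each repopulated library (0.03 to 0.23). It was lower in wild-type 1 (-1.26), wild-type 2 (-1.14) and wild-type 3 (-0.27). The median log2 fold change of that list was 0.33, and 0.62 without wild-type 4. Of 38 cell cycle genes 2 rose, and 2 rose adjusted over the list alone, with Cdk1 at 2.92-fold (camera adjusted p = 1.29e-05, and adjusted p = 0.263 with an estimated correlation). Without repopulated 3 Cdk1 had an edgeR adjusted p of 0.126 (0.000574 to 0.126 over all alternatives). Of 32 inflammatory genes 2 rose, and 6 rose adjusted over the list alone (camera adjusted p = 0.0443, and adjusted p = 0.228 with an estimated correlation). Its camera adjusted p was 0.0922, 0.0791, 0.0603 and 0.0723 without wild-type 1, wild-type 2, control 2 and repopulated 3, 0.0566 without the same 3 libraries, 0.0883 with Y-linked transcript status as a term and 0.0859 with the GC and length correction (0.00753 to 0.228 over all alternatives). Directional fry gave adjusted p-values of 0.137 for oxidative phosphorylation, 0.0517 for antigen presentation, 0.273 for interferon and 0.0517 for cell cycle genes.

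Of 29 homeostatic genes 3 fell and 26 did not pass, and 4 fell adjusted over the list alone (camera adjusted p = 0.000634, and adjusted p = 0.228 with an estimated correlation). Crybb1 fell 2.11-fold, while P2ry12 was at 5648 ± 1408 against 7993 ± 1006 CPM (edgeR adjusted p = 0.158) and Csf1r at 3714 ± 148 against 3984 ± 715 CPM (edgeR adjusted p = 0.863). Markers of border-associated macrophages, which line vessels and meninges, fell as a list of 16 genes with 1 up and 1 down, and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0122, and adjusted p = 0.528 with an estimated correlation). Without wild-type 1 the camera adjusted p was 0.0654 (8.33e-05 to 0.528 over all alternatives). Markers of neurons also fell as a list of 9 tested genes (camera adjusted p = 0.0443, and adjusted p = 0.528 with an estimated correlation). By edgeR 0 of them were called, 3 were lower at an unadjusted p under 0.05, and 3 fell adjusted over the list alone, with 1 called by DESeq2 and 0 by limma-voom. The median log2 fold change of that list was -1.44, and -0.16 without wild-type 3, which held most Snap25. Its camera adjusted p was 0.151 without wild-type 3, 0.0872 without repopulated 1 and 0.0514 without repopulated 3. With the GC and length correction it was 0.0859 (0.00519 to 0.528 over all alternatives). Directional fry gave adjusted p-values of 0.293 for border-associated macrophages and 0.295 for neurons.

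In this comparison 523 genes changed, 425 up and 98 down, with 10 egg transcripts of undecided source among those that rose. Of them, 475 had changed the same way in control microglia, 403 up and 72 down. Hpse, for one, was at 0.118 ± 0.0998, 30.9 ± 9.61 and 21.1 ± 6.77 CPM in wild-type, control and repopulated libraries. Independent lists would share 42.8 and 7.9, but both comparisons use the same wild-type libraries. With the wild-type libraries split into pairs, 1 pair for each comparison, the 6 assignments gave 238 to 417 such genes, where independent lists would share 18.3 to 59.9. The count of 523 was 305, 284 or 296 without repopulated 1, 2 or 3, with 286, 272 or 260 up and 19, 12 or 36 down. The 98 down were 57 without wild-type 2, 56 without control 1 and 207 by DESeq2, which called 573 up. The 475 shared genes were 290, 275 or 283 without repopulated 1, 2 or 3, of which 14, 11 or 31 had fallen, and 45, 32 and 42 had fallen without wild-type 2, control 1 and control 3. Without the 3 libraries with near absent Y-linked transcripts the counts were 289, 32 of them down, and 201, 13 of them down, with the latter resting on control 2 alone for the control group.

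**Figure D3:**
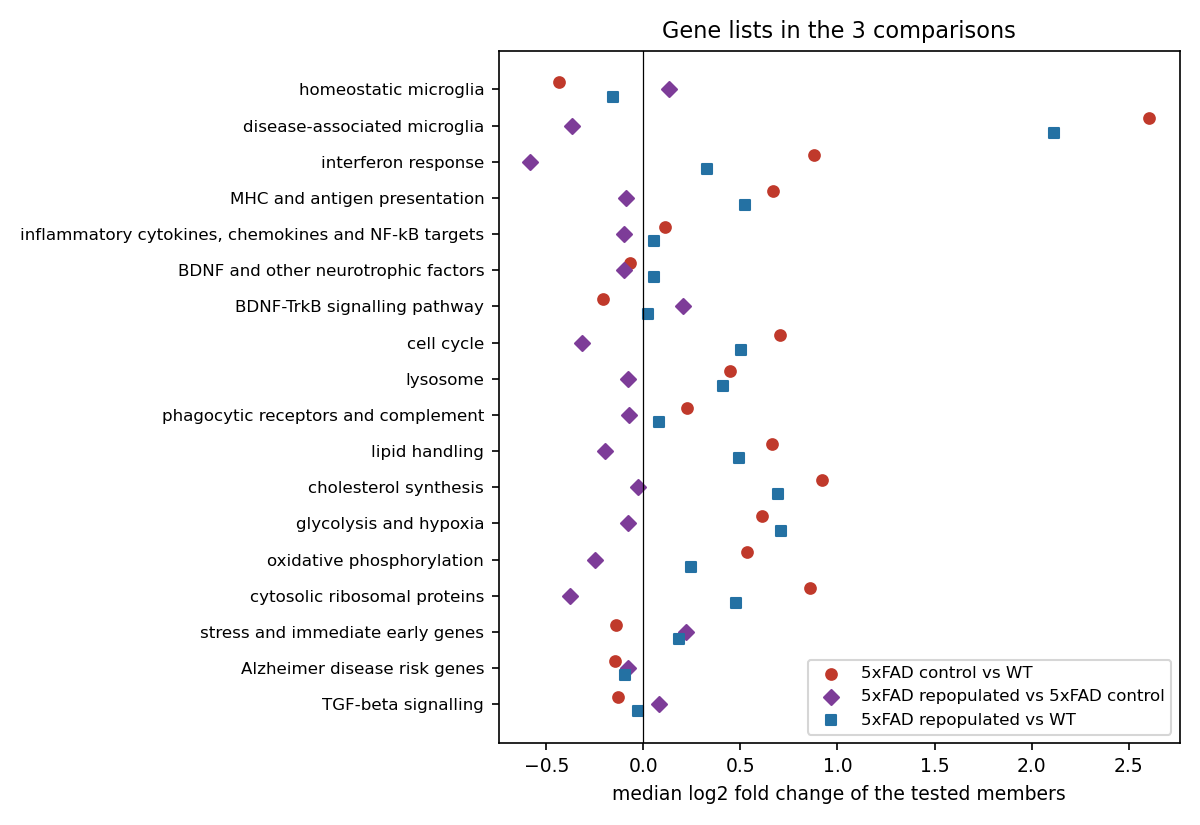
Median log2 fold change (x axis) of the tested members of each gene list, markers of other cell types left out, with circles for control against wild type, diamonds for repopulated against control and squares for repopulated against wild type. The disease-associated list stood at 2.60 for control and 2.12 for repopulated microglia against wild type, and at -0.37 between the 5xFAD groups.

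**Figure D4:**
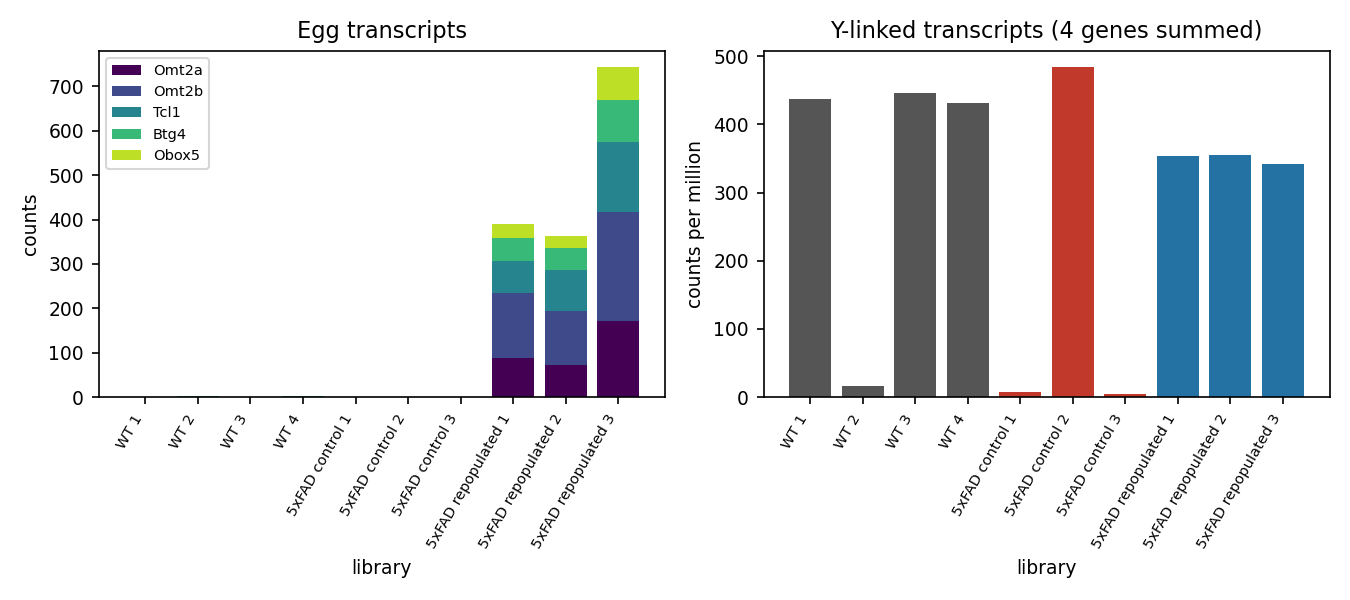
Stacked counts of the egg transcripts Omt2a, Omt2b, Tcl1, Btg4 and Obox5 on the left, and summed levels of 4 Y-linked transcripts in CPM of unscaled totals on the right, in each of the 10 libraries. Omt2b had 145, 123 and 244 counts in repopulated 1, 2 and 3 and no count in the other libraries.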

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

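The values for Y-linked transcripts, for egg transcripts other than Omt2b, for neutrophil transcripts other than Ngp and for Mbp, Slc1a2 and Hba-a1 were added after the data were seen. Of 105 values tested in the wild-type group, the only group of 4, 10 had 1 library far from the others. Chance alone gives about 1 in 20 for normally distributed values, which low counts are not. A gene counted in only 1 of the 4 libraries is always flagged, as Atp6v0d2 and Tcl1 were, so the 10 cannot be read as an excess over chance. In wild-type 3 Mbp (48.11 CPM, next 14), Slc1a2 (42.18 CPM, next 5.84), Hba-a1 (128.6 CPM, next 8.78), Snap25 (28.19 CPM, next 6.65), Ntrk2 (8.213 CPM, next 1.89) and Clec7a (72.65 CPM, next 31.3) stood above the other wild-type libraries. Ifi44 stood apart in wild-type 4 (1.258 CPM, next 0.193). Atp6v0d2 was counted only in wild-type 1 (0.04824 CPM) and the egg transcript Tcl1 only in wild-type 4 (0.04493 CPM). Wild-type 2 had 16.01 CPM of Y-linked transcripts, against 431 in the nearest wild-type library.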

How the results depend on the processing

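The Y-linked term, leaving out the 3 libraries with near absent Y-linked transcripts, the GC and length correction, and leaving out wild-type 3 and control 2 were chosen after the data were seen. Where fewer libraries or genes entered, that may be part of the shift, but the causes of the shifts were not tested. Single libraries left out gave 1315 to 2908 genes for control against wild type, 0 to 328 for repopulated against control (edgeR, 1321 at an unadjusted p under 0.05 for the 0) and 284 to 687 for repopulated against wild type. They gave 0 to 300 reversing and 275 to 628 persisting genes, r of -0.615 to -0.446, and 12 to 15, 4 to 9 and 12 to 16 lists. Differences in mean Bdnf CPM, in the same order of comparisons, were -0.491 to -0.119, -0.076 to 0.196 and -0.419 to -0.021. Each was shifted from its value with all libraries by less than the larger SD of the groups compared. Replicate numbers did not pair the libraries (correlations of -0.105 to 0.071, 0 closest to their own number), and a replicate block gave 1464 genes for control against wild type, 25 between the 5xFAD groups and 22 reversing. Between the 5xFAD groups DESeq2 gave 698 genes (573 reversing), limma-voom 125 (116), no filter 166 (152), the stricter filter 125 (120, r -0.618), the 2 groups alone 630, and an adjusted p of 0.1 355 (323). A 2-fold minimum gave 774, 35 and 281 genes, 28 reversing and 248 persisting. The Y-linked term gave 1 gene between the 5xFAD groups, 1 reversing and 7 lists. Leaving out the 3 libraries left control 2 as the only control library, assumed to vary like the other groups, and gave 1201, 388 and 289 genes, 340 reversing, 201 persisting, r -0.697 and 8 lists between the 5xFAD groups. Without wild-type 3 and control 2 there were 893 genes for repopulated against wild type, 775 persisting, r -0.611 and 12 lists between the 5xFAD groups, and the GC and length correction gave 8 such lists. Of 13, 4 and 14 lists called, camera with an estimated correlation called 1, 0 and 2, fry for change in either direction 25, 11 and 22, and directional fry 0 between the 5xFAD groups. Lists with no call gained one opposite to the direction of their test with all libraries for neutrophil markers without the 3 libraries (control 2 the only control, median 0.979 for control against wild type, -1.081 between the 5xFAD groups) and with the Y-linked term (-1.136 between the 5xFAD groups), and for lysosome genes without the 3 libraries (0.325 between the 5xFAD groups). The neutrophil median between the 5xFAD groups was -0.10 with all libraries, so its sign did not change there. Medians of other lists changed sign, with a call on either side, for phagocytic genes without the 3 libraries (-0.091) and neurotrophic factors with the Y-linked term (0.018) and the GC and length correction (0.174), each for control against wild type. They did so for astrocyte markers in control and repopulated against wild type without wild-type 3 (1.008 and 0.959) and without wild-type 3 and control 2 (1.181 and 0.959). Neutrophil markers had 2.561 between the 5xFAD groups without control 2 and 2.537 without wild-type 3 too. Over 1828, 1809 and 1833 reruns of named genes, 35, 145 and 78 lost a call, 11, 77 and 4 gained one and 0, 0 and 2 reversed. The 2 were Mbp, uncalled with all libraries, at 0.801 without wild-type 3, with or without control 2, against -0.02 with all and -0.272 without wild-type 2. Low counts and their spread between libraries, which were not separated, limit Bdnf, with 6 to 37 counts per group, 23 of the 37 in wild-type 3.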

Other observations

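Tests chosen only after the result was seen were those of GC content and length, of expression of egg genes by repopulated microglia, of neutrophil slopes, of sex, and the Y-linked term as an alternative. Several fixed lists did not move as a whole between control and wild-type microglia. Of 31 Alzheimer disease risk genes 6 rose and 6 fell, and 7 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.865). Of 36 stress and immediate early genes 4 rose and 5 fell, and 5 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.986). Atf3, a stress transcription factor gene, rose 2.98-fold, while Btg2 fell 2.09-fold. Of 17 TGF-beta signalling genes 3 rose and 2 fell, and 4 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.837).

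Among markers of other cell types in the same comparison, the camera adjusted p was 0.837 for border-associated macrophages (0.0391, median -0.56, without wild-type 3 and control 2, 0.0391 to 0.966 over all alternatives) and 0.177 for monocytes and recruited macrophages (0.0066, median 0.84, with Y-linked transcript status as a term, 0.0066 to 0.628 over all alternatives). It was 0.837 for neutrophils (0.0331, median 0.98, without the 3 libraries with near absent Y-linked transcripts and so with control 2 as the only control library, 0.0331 to 0.966 over all alternatives) and 0.986 for T, NK and B cells. It was 0.532 for astrocytes (0.00872 with a median log2 fold change of 1.01 without wild-type 3, against -0.40, 0.00872 to 0.954 over all alternatives) and 0.376 for oligodendrocytes and their precursors (0.0167, median -4.21, with control 2 again the only control library, 0.0167 to 0.936 over all alternatives). Endothelial and mural cells had 0.734 (0.00749 by directional fry, 0.00749 to 0.989 over all alternatives), and choroid plexus, ependymal cells and erythrocytes 0.837 (0.0255, median -3.58, with a replicate block, 0.0255 to 0.989 over all alternatives). Median, mean and camera direction were not all of 1 sign for neurotrophic factors, TGF-beta signalling, neutrophils, T, NK and B cells, astrocytes and endothelial and mural cells in this comparison, for antigen presentation, Alzheimer disease risk genes, neutrophils and endothelial and mural cells between the 5xFAD groups, and for the BDNF-TrkB pathway, Alzheimer disease risk genes, TGF-beta signalling, monocytes, T, NK and B cells, astrocytes and oligodendrocytes between repopulated and wild-type microglia. Flt1, a VEGF receptor gene on the endothelial list, rose 16.1-fold, from 1.45 ± 0.777 to 23.5 ± 3.63 CPM, while Cldn5 of the same list had at most 0.49 CPM in any library.

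Some lists without a call between repopulated and wild-type microglia gained one under an alternative. Stress and immediate early genes (camera adjusted p = 0.0618) had 0.0143 without wild-type 4, 0.0339, 0.0408 and 0.0346 without control 1, 2 and 3 and 0.00246 without repopulated 3 (0.00246 to 0.528 over all alternatives). Neurotrophic factors (camera adjusted p = 0.0708) had 0.0191 without wild-type 3 (0.00411 to 0.335 over all alternatives), and phagocytic genes (camera adjusted p = 0.123) 0.0485 without wild-type 3 and 0.043 without repopulated 1 (0.0344 to 0.533 over all alternatives). Astrocyte markers (camera adjusted p = 0.542) had 0.00194, median 0.96 against -0.48, without wild-type 3 (0.00194 to 0.912 over all alternatives), and neutrophil markers (camera adjusted p = 0.542) 0.0395 without repopulated 3 (0.0391 to 0.996 over all alternatives). Choroid plexus, ependymal and erythrocyte markers (camera adjusted p = 0.472) had 0.000689, median -4.35, with a replicate block (0.000689 to 0.688 over all alternatives), and endothelial and mural markers (camera adjusted p = 0.472) 0.00845 by directional fry (0.00845 to 0.858 over all alternatives).

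Egg transcripts appeared in the 3 repopulated libraries: Omt2a, Omt2b, Tcl1, Btg4 and Obox5 had 333, 512, 324, 195 and 131 counts there, and 0, 0, 1, 5 and 0 in the 7 other libraries. Of 37 further egg genes, listed before their counts were seen, 13 had a count in every repopulated library and none elsewhere, against at most 1 for any other 3 libraries among 120 sets, which is consistent with carry-over of RNA or reads from egg or early embryo material. Zp2 and Zp3, abundant in growing oocytes, had only 3 and 3 counts there, and Gdf9 had 887 counts in the other libraries, so the listed genes do not all follow 1 pattern. The 37 genes were chosen after egg transcripts had been seen in these libraries. Some of the 13, such as Tcl1b1 and Obox1, belong to families of egg genes already seen. Estimated counts can split reads between near-identical genes, so such members are not independent of the first genes. Expression by repopulated microglia cannot be told apart from carry-over, since the design holds 1 repopulated group.

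The 71 genes between the 5xFAD groups had a median absolute log2 fold change of 1.00 (median SE 0.19). Their median coefficient for Y-linked status, signed for each gene toward the control group, was -0.064 (SE over genes 0.036, which takes the genes as independent). The genes were called without this term, which favours genes with a small spread between the control libraries. Those libraries differed in Y-linked status, so a small coefficient cannot decide whether that status is a cause. With the term the median change was 1.06 with a median SE of 0.23, and all but 1 call ended, for a reason not tested. Changes followed GC content across tested genes (rho 0.436, and 0.002 after correction). The corrected median change of the 71 genes was 0.84 of the uncorrected, and 57 were still called. The genes were chosen by their uncorrected change in the same libraries. These values therefore show only that the fitted trend did not make up most of that change. The 10 splits of the 6 libraries are too few for a share under 0.05: the real one gave 71 genes and the highest other 0 by edgeR (75 to 715 at an unadjusted p under 0.05; other tools were not run). The depletion and repopulation itself stays open as an untested biological difference.

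For control against wild type 1 of 35 splits of the 7 libraries, the real one, gave as many as 2264 genes, and the highest other gave 1249. For repopulated against wild type 1 of 35 gave as many as 523, and the highest other gave 215. In each case this is the smallest share that 35 splits allow, so chance is unlikely as the source but is not excluded. Both of the highest others set wild-type 1, 2 and 4 against the rest.

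Neutrophil transcripts were low in the 3 libraries with near absent Y-linked transcripts: S100a8 was at 8.25 to 10.92 CPM there and at 28.29 to 149.05 CPM in the other 7. The log2 levels of S100a9, Camp, Ngp and Ltf followed S100a8 with slopes of 0.979, 0.988, 0.892 and 0.947 over the 10 libraries, which is consistent with neutrophil RNA or cells in the sorted samples, although a CD45low gate should leave neutrophils out. The Y-linked counts differed as they would between female and male animals, with Ddx3y at 0, 1 and 49 counts in control 1, control 3 and wild-type 2. The labels give a sex for 0 samples, so sex of the animals cannot be told apart from neutrophil content.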
